A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

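The series holds 14 samples of polyA RNA from diploid SK1 yeast, 10 of a wild-type meiotic time course and 4 controls at 8 h, 2 of them with a deletion of ime4. The deposited values are cleavage efficiencies per site, a fraction from 0.004 to 1 for each library, with missing values, made by the authors by treating RNA with MazF, which the table's column headers name. Per the submitters' processing notes, STAR 2.5.3a and bedtools 2.26.0 were used. Which reads counted as cut or uncut, the coverage behind a value, the rule behind missing values, how sites were chosen and the genome build are not given in the sources used here. Depth per library is therefore unknown, and the number of sites with a value is given in its place.

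Columns were tied to samples by the hour in their names. The labels' design text describes time points 1 h apart, while one is at 3.5 h. The table also holds 4 columns whose names match no label, and these were used in no step. The 4 control samples could therefore not be analysed here, and the planned comparisons of the ime4 deletion with wild type, of the 8 h library with the wild-type control, of slopes with the effect of the deletion, and of motif groups were not made.

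The table has 1198 rows. Removing 14 repeats of a position listed under another gene left 1184 sites in 1009 genes. Of 1020 gene identifiers, 1002 matched locus tags of the R64 reference, which was used for names only. The listed coordinates do not belong to R64, since 24 of the sites start an ACA motif there, and at most 29 with any shift of up to 2 bases. No sequence, UTR or exon was therefore assigned to a site, and coordinates are printed as deposited.

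The trend over time was fitted per site with limma 3.58.1 in R 4.3.3, as a linear model on the hour of the fraction without scaling, with a mean-dependent prior variance, over the 591 sites with values in at least 8 libraries. Late (5, 6, 7 and 8 h) and early (0, 1 and 2 h) libraries were compared by a contrast in a model of 3 windows, for the 496 sites that also had at least 2 values in each window. P-values were adjusted by Benjamini-Hochberg at 0.05. Of 16 gene lists fixed before the data were examined, those with at least 5 complete sites were tested with camera at a preset correlation of 0.01. Correlations over libraries used 100000 permutations in SciPy 1.17.1 under Python 3.11.15. The share of sites with a value at 0 h was compared between each list and all other sites by Fisher's exact test.

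Sites were named by a rule fixed before the data were examined: the 12 steepest falls and 6 steepest rises that passed the trend test, up to 4 sites per list with the smallest adjusted p, and every site of the methylation machinery and of RME1, IME1 and IME2. Other named sites are said to have been chosen later, and the remaining 5 of the 18 falling sites are named to complete that count.

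The trend step was tested on simulated data for the same 591 sites, with normal noise and no ceiling at 1, in 5 draws. It called 46.8% of sites simulated to fall by 0.02 per hour, 70.8% at 0.04, 97.2% at 0.08 and 100% at 0.12, and 4.37% of its calls were false. Over the 5 draws there were 250 simulated sites at each of these falls and 1955 with no fall. So large a share of falling sites makes the adjusted threshold easier to pass, so these percentages may be too high for the real data. Alternatives covered the scale (logit with values held within 0.01 to 0.99, arcsine square root), shifting or scaling libraries to 1 median, the variance model, filters on missing and low values, a spline with 3 degrees of freedom, ranks of the hour, other windows and leaving out each library. The alternatives and tests added after seeing the data are named where they are reported. Neighbouring times of 1 course are not independent replicates, so the p-values treat scatter around the line as the error.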

Results

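Cleavage of yeast mRNA by MazF, an RNA endonuclease that cuts before an ACA motif when its first A is not methylated, was followed in diploid SK1 cells for 8 h after meiosis was induced. SK1 is a laboratory strain that enters meiosis rapidly and in near synchrony. The labels give the cells a disrupted ndt80, the gene of the transcription factor needed to leave pachytene of the first meiotic division. The table held 1 library at each of 0, 1, 2, 3, 3.5, 4, 5, 6, 7 and 8 h, and gave for each of 1184 distinct sites in 1009 genes a cleavage efficiency, a fraction from 0.004 to 1 that is higher where more of the RNA was cut. The number of reads behind a value is unknown, so no counting interval could be given. The number of sites with a value was 299 at 0 h, 613 at 1 h, 988 at 2 h and 891 at 3 h. It was highest at 3.5 h, with 1171 sites, then 1132 at 4 h, 1052 at 5 h, 1054 at 6 h, 740 at 7 h and 626 at 8 h. There were no replicates at any hour, and the labels do not say whether the libraries came from 1 culture, so each p-value over time measures the scatter of single libraries around a fitted line or window mean. Sites are named by gene and by the position within the gene that the table gives. Chromosome coordinates are those of the table, whose genome build is not given in the sources used here. A site within NDT80 (position 1858) had a value in 9 of the 10 libraries, from 0.830 at 2 h to 0.954 at 3 h. The labels do not say which part of the gene was replaced, so this site does not check the genotype.

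The first question was how cleavage moved over the course at the sites with a value in all 10 libraries, which were 214 of the 1184. That set held 7 of the 8 listed sites of glycolysis and fermentation. It held 0 of the 22 of early meiotic recombination and synapsis, 0 of the 6 of regulators of meiotic entry and 0 of the 26 of DNA replication and repair. Over the 214 sites with a value in all 10 libraries, the median cleavage efficiency was 0.926 at 0 h, 0.890 at 2 h, 0.880 at 4 h and 0.855 at 6 h, the lowest of the course. It was 0.871 at 7 h and 0.872 at 8 h. The share of these sites cut by less than 0.5 was 1.87% at 0 h, 8.88% at 6 h and 6.07% at 8 h. The lower quartile of the sites went from 0.866 at 0 h to 0.758 at 6 h, while the upper quartile went from 0.984 to 0.909. The median fell with the hour, with Pearson's r = -0.825 (two-sided permutation p = 0.0024, adjusted p = 0.0048 over 2 measures, n = 10 libraries) and Spearman's rho = -0.770 (permutation p = 0.0131, adjusted p = 0.0131). Without the libraries farthest from the median hour, at 0 h and 8 h, r was -0.845. Spearman's rho without any 1 of the 0, 1, 2 or 3 h libraries was -0.683, with a permutation p of 0.0505.

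**Figure D1:**
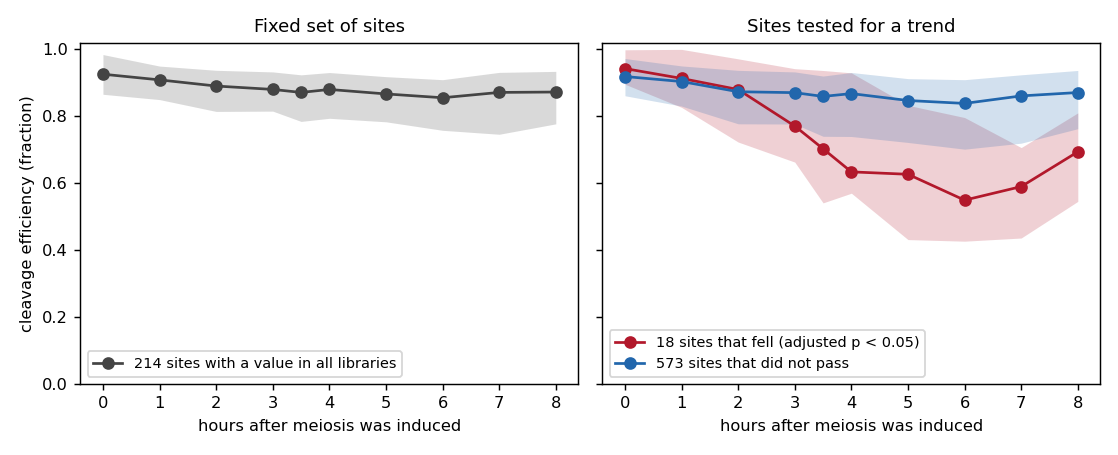
Cleavage efficiency (fraction, vertical axis) against hours after induction of meiosis, as medians over sites (points) with the quartiles over sites (shaded), from 1 library per hour. Left, the 214 sites with a value in all libraries, with medians from 0.926 at 0 h to 0.855 at 6 h. Right, the 18 sites that fell, which were picked for their fall, with medians from 0.943 at 0 h to 0.549 at 6 h, and the 573 other tested sites. Of the 18, 8 had a value at 0 h and 11 at 8 h, so medians at different hours are over different sites.

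The next question was which sites changed steadily over the course. Among 591 sites in 531 genes with values in at least 8 libraries, 18 fell along a straight line in the hour and 0 rose. The steepest slope among the 18 was in YCK1, which encodes a casein kinase I of the plasma membrane. Its site at position 1763 went from 1.00 at 0 h to 0.487 at 3.5 h and 0.345 at 6 h. It had no value at 7 h or 8 h, so its slope covers 0 to 6 h only. Sites in ERG13 (HMG-CoA synthase, of sterol synthesis), ACH1 (a mitochondrial acetyl-CoA hydrolase) and BLM10 (a proteasome activator) also fell. A site in PCH2, the ATPase of the meiotic recombination checkpoint, was cut by 0.686 at 1 h and by 0.295 at 8 h. The median over the 18 sites was 0.549 at 6 h. Over the 8 of them with a value at 0 h, it was 0.943 at 0 h and 0.562 at 6 h. Over the 11 with a value at 8 h, the median was 0.664 at 6 h and 0.694 at 8 h, and 4 of the 11 were higher at 8 h than at 6 h.

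The fall in YCK1 (YHR135C, chromosome 8, position 372985, minus strand) was -0.108 ± 0.0166 per hour (slope ± SE, limma, adjusted p = 0.0307, 8 libraries). CVM1 (YMR160W, chromosome 13, position 567046), which encodes a protein of contacts between vacuole and mitochondria, had a slope of -0.0852 ± 0.0190 per hour. Its value was 1.00 at 1 h and 2 h, 0.478 at 6 h and 0.590 at 7 h. ERG13 (YML126C, chromosome 13, position 27340) was cut by 0.771 at 1 h and by 0.267 at 7 h, a slope of -0.0851 ± 0.0161. ACH1 (YBL015W, chromosome 2, position 190114) went from 0.884 at 2 h to 0.429 at 6 h, and BLM10 (YFL007W, chromosome 6, position 134372) from 0.646 at 2 h to 0.261 at 7 h. The small open reading frame YDR524C-B (chromosome 4, position 1482669) went from 0.955 at 0 h to 0.336 at 6 h and stood at 0.514 at 8 h. REG1 (YDR028C, chromosome 4, position 510323), which encodes a phosphatase subunit needed for glucose repression, was at 0.901 at 0 h, 0.401 at 5 h, 0.574 at 6 h and 0.577 at 8 h. MLO50 (YLR049C) had a slope of -0.0551 ± 0.0130, ATE1 (YGL017W), the arginyl-tRNA-protein transferase gene, -0.0546 ± 0.0115, and AIM41 (YOR215C) -0.0504 ± 0.0110. The sites in CVM1, ERG13, ACH1 and BLM10 had no value at 8 h, so slopes were ranked over unlike hours. In the fit from 0 to 6 h, added after seeing the data, the slope was -0.108 in YCK1 and -0.111 in both CVM1 and YDR524C-B. It was -0.124 in SPO24, whose site did not pass over all hours. HAP4 (YKL109W, chromosome 11, position 235105), a subunit of the activator of respiratory genes, was at 1.00 at 2 h and 0.706 at 7 h, with a slope of -0.0508 ± 0.00871 and an adjusted p of 0.0307. Smaller falls that passed were in PEP4 (vacuolar proteinase A), ASI1, CYC7 (an isoform of cytochrome c), DSE3, NNK1 and TMA10, with slopes from -0.0401 in PEP4 to -0.0121 in TMA10. Adjusted p-values of the 18 sites ran from 0.0307 to 0.0472, all near the threshold of 0.05. A value of exactly 1 was more common in the first libraries: 48 of 299 sites at 0 h and 111 of 613 at 1 h. At 6 h it was 73 of 1054, and at 8 h 72 of 626. With depth unknown, a start at 1.00, as in YCK1 and CVM1, cannot be told apart from a value resting on few reads. Some falling sites also shared a value with another site to all digits given, such as ATE1 and MLO50 at 3 h (0.771), and the precision of such values is unknown. At an unadjusted p under 0.05, 96 sites had a falling and 8 a rising slope. The slope was negative at 430 of the 591 sites (72.8%), with a median of -0.00614 per hour, against a median residual SD around the line of 0.0594.

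**Figure D2:**
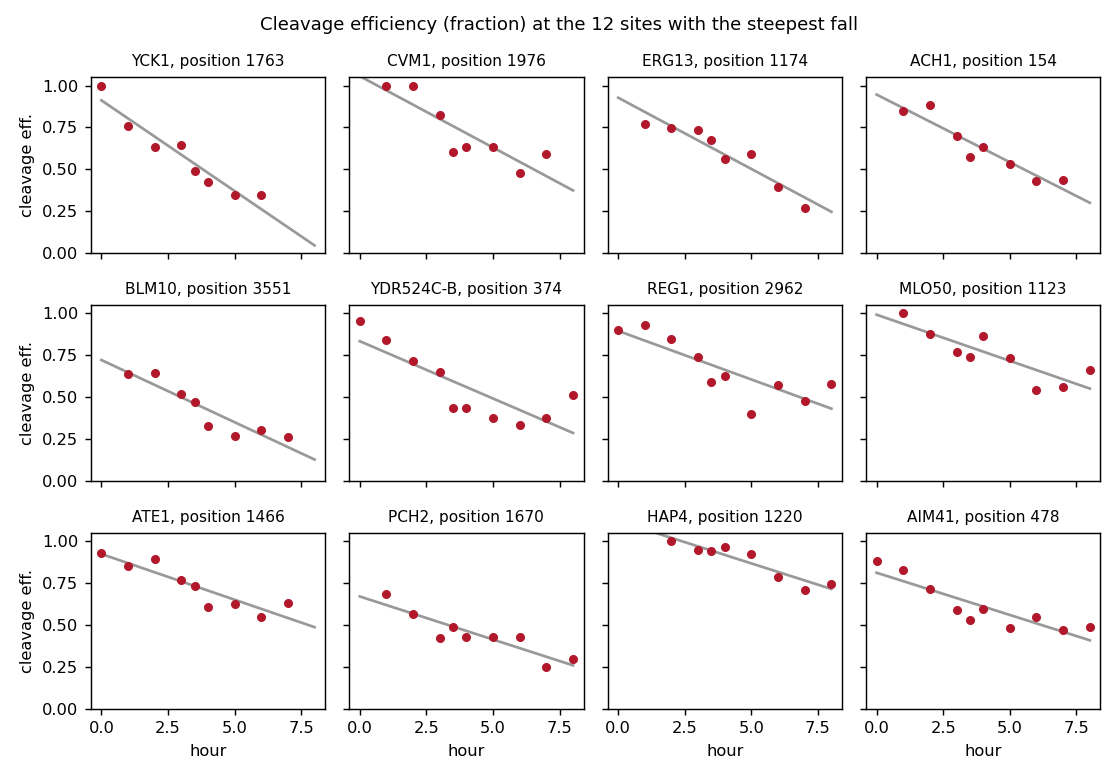
Cleavage efficiency (fraction) against hour for the 12 sites with the steepest falls that passed the test, with 1 point per library and the fitted line. Where a site had no value at an hour, its line rests on the other hours. YCK1 went from 1.00 at 0 h to 0.345 at 6 h, and YDR524C-B stood higher at 8 h (0.514) than at 6 h (0.336).

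The number of single sites past the threshold rested on every library: limma called 0 sites without any 1 of the 1, 2, 3, 3.5, 4 or 5 h libraries (lowest adjusted p from 0.0522 to 0.0783), 5 without 0 h, 2 without 6 h, 8 without 7 h and 50 without 8 h. In those fits 70 to 134 sites had a falling and 4 to 12 a rising slope at an unadjusted p under 0.05. The count was 0 after shifting or scaling the libraries to 1 median, 0 over all 1130 sites with at least 4 values, 8 over the 214 complete sites, 32 with a spline and 55 from 0 to 6 h only, the last and the 214 sites being choices made after seeing the data.

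Late libraries (5 to 8 h) were then compared with early ones (0 to 2 h), which does not ask for a straight line. Of 496 sites, 18 were lower late and 0 were higher (103 at an unadjusted p under 0.05, limma), with a median difference of -0.331 over the 18 sites (from -0.440 to -0.175). The largest difference that passed was in SPO24, a short gene named for sporulation, at -0.440 (limma, adjusted p = 0.0332). Its site (YPR036W-A, chromosome 16, position 659341) was cut by 0.985 at 0 h, 0.551 at 2 h, 0.257 at 3.5 h and 0.413 at 8 h, so that its 4 late values all lay below its 3 early ones. OLE1, the fatty acid desaturase gene, was lower by -0.417 (adjusted p = 0.0430), from 0.771 at 0 h to 0.142 at 6 h. INO1, which encodes inositol-3-phosphate synthase, was lower by -0.348 (adjusted p = 0.0444), and SAE3, whose product helps load the meiotic recombinase Dmc1, by -0.349 (adjusted p = 0.0444).

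Also lower late were GFA1, of amino sugar synthesis (-0.313), FAA1, a fatty acyl-CoA synthetase (-0.312), PRE1, a subunit of the proteasome core (-0.306), and WBP1, of the oligosaccharyl transferase (-0.263). These 4 and SPO24, OLE1, INO1 and SAE3 are the 8 sites that passed here and not with a straight line, and were picked for naming after their values were seen. The other 10 of the 18 had passed both tests, which used the same libraries. Over all 496 sites the median difference was -0.0419, with a median SE of 0.0474. The count was 0 without any 1 of the 1, 3.5, 6 or 7 h libraries. It was 14 without 0 h, 10 without 2 h, 8 without 3 h, 6 without 4 h, 6 without 5 h and 29 without 8 h. Only 263 sites could be tested without 1 h and 253 without 2 h, against 476 to 496 without any other library. The count was also 0 with the 3 h library among the early ones, and 0 of 591 sites with at least 1 value per window in place of 2, a setting added after seeing the data. These fits with 0 calls had 40, 95, 86, 97, 102 and 115 sites at an unadjusted p under 0.05. With libraries shifted to 1 median 7 sites were lower and 4 higher, and with libraries scaled to 1 median 16 were lower and 7 higher.

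The genes of meiosis were looked at as groups fixed before the data were examined. Of 13 tested sites in genes of early meiotic recombination and synapsis, 10 had a negative slope and 1 fell, the site in PCH2, with 1 also when adjusted over the list alone and 4, all with a negative slope, at an unadjusted p under 0.05 (limma). HOP2, which acts in the pairing of homologous chromosomes, had a slope of -0.0399 ± 0.0130 (adjusted p = 0.131), with values of 0.935 at 1 h and 0.638 at 6 h. SAE3 had a slope of -0.0503 ± 0.0181 (adjusted p = 0.182), with 0.780 at 1 h, 0.251 at 6 h and 0.434 at 8 h. SPO22, of the synapsis initiation complex, was at 0.866 at 2 h and 0.692 at 8 h (adjusted p = 0.197). The other tested sites of PCH2 (position 1283), HOP2 (852) and SPO22 (1796) were nearly flat, with slopes of -0.00390, -0.00321 and 0.00228. The median slope over the 13 sites was -0.00390, against -0.00614 over all 591 tested sites, of which 72.8% had a negative slope. No site of this list had a value at 0 h, while part of the 591 did, so these medians cover unlike hours. Among 3 tested sites in regulators of meiotic entry none passed (1 at an unadjusted p under 0.05, limma, and 0 adjusted over the list alone). RIM4, an RNA-binding repressor of translation, was at 0.862 at 1 h and 0.511 at 4 h. RIM11, a kinase that acts on the regulator Ume6, was at 1.00 at 1 h, 0.727 at 5 h and 1.00 at 8 h. In the methylation machinery and reader list, VIR1, a subunit of the methyltransferase complex, and PHO92, which binds methylated mRNA, had slopes of 0.000456 ± 0.00257 and 0.000956 ± 0.00251 per hour. Their values lay between 0.953 and 1.00 throughout. The table used here had no row for IME4, RME1, IME1 or IME2. The 3 sites in NDT80 targets of middle sporulation had too few values to be tested.

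Of 7 tested sites of glycolysis and fermentation, 6 had a negative slope and none passed (1 at an unadjusted p under 0.05). The glycolytic genes ENO2, CDC19 and TPI1 were at 0.436, 0.563 and 0.563 at 7 h, against 0.847, 0.939 and 0.968 at 6 h and 0.769, 0.663 and 0.769 at 8 h. At 7 h CDC19 and TPI1 had the same value to all digits given, as did ENO2 and ACH1. ENO2 and TPI1 also shared a value at 8 h. Shared values were not particular to this list or to these hours, as INO1 and SAE3 were both at 0.780 at 1 h, and ATE1 and MLO50 both at 0.771 at 3 h. The reads behind these values are unknown, so their precision cannot be given. ADH1, alcohol dehydrogenase, was at 0.924 at 0 h and 0.833 at 8 h. Of 11 sites of acetate use, the glyoxylate cycle and gluconeogenesis, 8 had a negative slope and 0 passed, with 0 at an unadjusted p under 0.05. In this list ICL1, isocitrate lyase, was at 0.907 at 0 h and 0.754 at 8 h, and MDH2, malate dehydrogenase, at 0.835 and 0.772. JEN1, a lactate and pyruvate carrier, was at 0.927 and 0.849. Of 7 sites of respiration 5 had a negative slope and 0 passed (0 unadjusted), with MDH1 at 0.906 at 2 h and 0.687 at 8 h, and ATP2, a subunit of ATP synthase, at 0.802 at 0 h and 0.684 at 8 h. Of 7 sites of heat shock and general stress 6 had a negative slope and 0 passed (0 unadjusted), with GPH1, glycogen phosphorylase, at 0.972 at 0 h and 0.836 at 6 h.

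Of 5 tested sites of autophagy and vacuolar proteases, 1 fell, in PEP4, and 2 when adjusted over the list alone, with CPS1, a vacuolar carboxypeptidase (3 unadjusted, 1 of them with a positive slope). CPS1 was at 0.478 at 0 h, 0.181 at 1 h and 0.0841 at 6 h (adjusted p = 0.0722 over all sites). VMA2, of the vacuolar proton pump, had a positive slope of 0.00825 ± 0.00349 (adjusted p = 0.236). Of 10 sites of DNA replication and repair 6 had a negative slope and none passed (2 unadjusted). MCM3, of the replicative helicase, was at 0.821 at 1 h and 0.506 at 6 h, and the cohesin loader SCC2 at 0.747 at 2 h and 0.960 at 8 h. Of 5 sites of translation factors 4 were negative and none passed (1 unadjusted), with TIF3 at 0.874 at 0 h, 0.599 at 6 h and 0.737 at 8 h. Of 3 histone sites 1 was negative and none passed (0 unadjusted), and HTA1, histone H2A, was cut little at all hours, from 0.0202 at 0 h to 0.157 at 6 h. In the mitotic growth list, which stands for cells that had not entered meiosis, all 3 tested sites were negative and none passed (1 unadjusted). The site in PMA1, the plasma membrane proton pump, was at 0.951 at 0 h, 0.398 at 5 h and 0.771 at 7 h. No site of ribosomal proteins, ribosome biogenesis or the haploid and mating list had enough values to be tested, from 5, 3 and 2 sites. No list had a rising site that passed.

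As sets, 3 lists had at least 5 complete sites, and limma's camera found none to differ in slope from the other sites. The adjusted p was 0.795 for the 7 sites of glycolysis, 0.795 for the 11 of acetate use and 0.908 for the 5 of respiration, and 0.815, 0.815 and 0.909 with an estimated correlation. For acetate use camera's direction was up, while its median slope over all 11 sites was -0.00393, since camera compares with other sites. Against no change at all, limma's fry gave a downward direction for all 3, with adjusted p of 0.0228, 0.0236 and 0.0118, which does not compare a list with other sites.

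Groups also differed from the other sites in the share with a value at 0 h, as tested after the pattern was seen. At 0 h, 0 of 22 sites in genes of early meiotic recombination had a value, against 299 of 1162 other sites (two-sided Fisher's exact test, adjusted p = 0.00448 over 10 lists). By 3.5 h all 22 had one, and 13 did at 8 h. None of 26 sites of DNA replication and repair had a value at 0 h (adjusted p = 0.00282), 23 had one at 2 h, 26 at 3.5 h and 10 at 8 h. A value at 0 h was present for 7 of 8 sites of glycolysis (adjusted p = 0.00195), 11 of 15 of acetate use (adjusted p = 0.00114), 7 of 9 of heat shock (adjusted p = 0.00343) and 5 of 7 of respiration (adjusted p = 0.0220). Autophagy, with 5 of 9, had an adjusted p of 0.0718, ribosomal proteins, with 3 of 5, 0.132, and translation factors, with 2 of 8, and regulators of meiotic entry, with 1 of 6, 1.0. The rule behind missing values is not given in the sources used here, and sites of 1 gene are not independent in these tests.

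**Figure D3:**
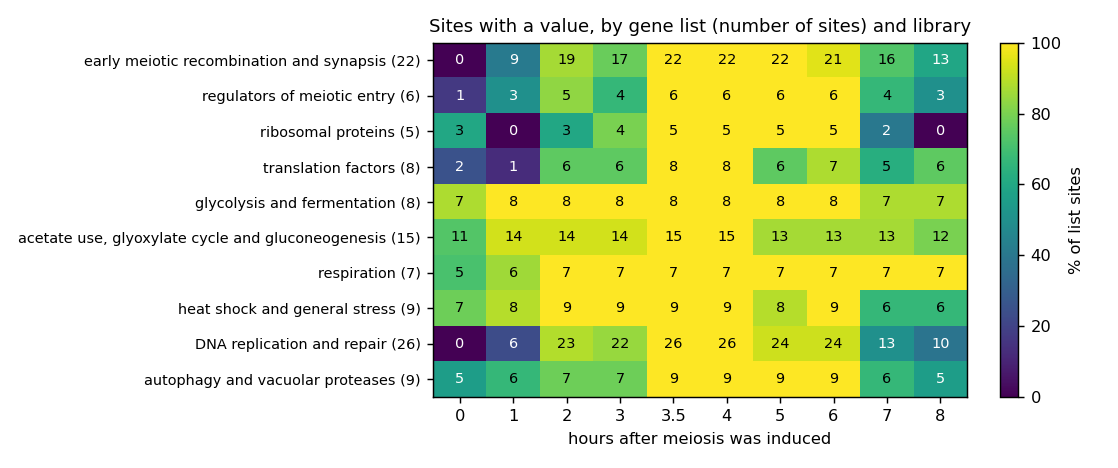
Number of sites with a value (printed in each cell) and its share of the list's sites (colour, percent) for 10 gene lists (rows, with their number of sites) and 10 libraries (columns, hours after induction). The lists of early meiotic recombination and of DNA replication have 0 sites at 0 h and all of theirs at 3.5 h.

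Neighbouring sites of 1 gene did not always move together. In PEP4 the site at position 1144 (chromosome 16, position 269299) fell from 1.00 at 0 h to 0.694 at 8 h, while the site at 1434, 290 bases on, was at 0.891 and 0.863. Position 1144 was still at 0.923 at 5 h and 0.855 at 6 h, and its lowest values were at 7 h (0.673) and 8 h. From 0 to 6 h its slope was -0.0196 per hour, against -0.0401 over all hours, and that of position 1434 was -0.00275. In BLM10 the site at 3551 fell, and the one at 3407, 144 bases away, had a slope of 0.00336. The difference between the sites of a pair changed with the hour in both genes (permutation test of the slope of the difference, adjusted p = 0.0142 each over 63 pairs), the only 2 pairs that passed. The sites of REG1, at 2962 and 3300, did not pass (adjusted p = 0.0567), although their slopes were -0.0579 and -0.00341, and nor did those of MDL1 (0.0567). This test was designed after the contrast in PEP4 had been seen.

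**Figure D4:**
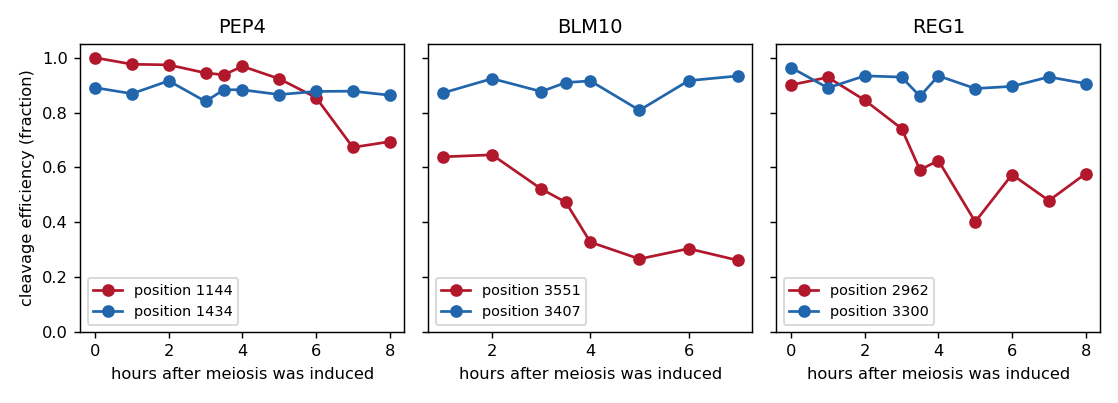
Cleavage efficiency (fraction) against hour at pairs of sites in PEP4, BLM10 and REG1, with 1 point per library joined by lines. PEP4 position 1144 ended at 0.694 and position 1434 at 0.863, and the difference between sites changed with the hour in PEP4 and BLM10 but did not pass the test in REG1.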

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

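Settings that leave out both the 7 h and 8 h libraries, take only sites complete in the 10 libraries, use windows of 3 to 6 h against 0 and 1 h, ask for at least 1 value per window, or test lists on incomplete sites were chosen after seeing the data. The direction of the trend was downward for all called sites in every linear setting, while the count was not stable. From 18 falling sites it went to 0 with libraries shifted to 1 median and 0 with libraries scaled (102 and 101 sites at an unadjusted p under 0.05), 0 over all sites with at least 4 values (195 unadjusted), 8 over complete sites, of which 6 were among the 18, 32 with a spline, of which 5 were, and 55 without 7 and 8 h, of which 14 were. More sites entered the correction with at least 4 values, but the cause was not tested for that setting or for the others. Leaving out 1 library gave 0 to 50 sites. The remaining settings gave 16 to 24. Late against early, 18 lower and 0 higher sites became 11 calls with libraries shifted (7 lower, 4 higher) and 23 with libraries scaled (16 lower, 7 higher). All calls were lower in the other settings, with 10 over all fitted sites, 0 for 5 to 8 h against 0 to 3 h (102 unadjusted), 0 with at least 1 value per window (115 unadjusted, 591 sites tested in place of 496), 0 to 29 without 1 library and 13 to 22 in the rest, and the cause was not tested. The correlation of the median with the hour ran from -0.892 to -0.751 without 1 library, was -0.716 over all sites measured, -0.785 with means and -0.966 for 0 to 6 h. Of gene lists, fry called 3 where camera called 0, since fry compares with no change. Camera on incomplete sites gave 0 of 8 lists, 0 of 8 with estimated correlation, and 0 of 10 with at least 4 values. No paired analysis was possible because the columns of the wild-type and deletion samples that share replicate numbers could not be tied to labels, and the alternatives planned for those samples, the wild-type controls added at 8 h and sites complete in all 14 libraries were not run. Depth is unknown, so its limits could not be computed.

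Slopes that turned sign were all of sites that had not passed, and the cause was not tested. On the logit scale FKS1 was at 0.0128, and on the arcsine scale FKS1 was at 0.00231 and EFT2 at 0.00249. With libraries shifted, the slopes per hour were 0.00500 for NDT80, 0.000213 for YEF3, 0.00210 for EFT2, 0.000495 for ADH2, 0.00204 for HHO1, 0.00441 for PEP4 at 1434, 0.00423 for GAS1 and 4.52e-05 for FKS1. With libraries scaled, they were 0.00508 for NDT80, 0.00247 for EFT2, 0.000700 for ADH2, 0.000172 for KGD2, 0.00201 for HHO1, 0.00427 for PEP4 at 1434, 0.00387 for GAS1 and 0.000270 for FKS1. VIR1 was at -7.18e-05 with ranks. Without 7 and 8 h PHO92 was at -0.000729, VIR1 at -0.00336, CDC19 at 0.00303 and TPI1 at 0.00865. Leaving out 1 library gave -0.00604 to 0.00440 for NDT80, -0.0162 to 0.00456 for YEF3, -0.00779 to 0.00393 for HHO1, -0.00118 to 0.00332 for PHO92, -0.00277 to 0.0226 for CSE4, -0.0190 to 0.00653 for GAS1, -0.000716 to 0.00190 for VIR1 and -0.00353 to 0.00231 for EFT2. Over the named sites and settings, 1000 values kept direction and side of the threshold, 157 lost and 12 gained a call.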

Other observations

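Most tests below were chosen after the result was seen: those on the set of listed sites, on scaling, on other splits into windows, on the excess of falling over rising sites, on the 18S rRNA site, on the shapes of the spline sites and on lowest values. The spline fit was planned, and the tests on the number of sites in other orders of the libraries, on 8 h and on sites of 1 gene were written before. A curve found sites that a line did not. A spline of the hour called 32 sites, 30 with a negative and 2 with a positive linear slope, and the lowest value lay at 3 to 6 h in 21 of them. Of the 29 with a value at 8 h, 24 were higher at 8 h than at 6 h. These sites were picked by a curve fitted to the same 8 h values, so that count is no separate evidence of a return. Of 175 sites that had not fallen by over 0.1 up to 5 h, 107 (61.1%) were also higher at 8 h than at 6 h. SPO24 had the smallest adjusted p (limma F test, 0.000155), followed by OLE1 (0.00182) and YDR524C-B (0.00244). RIM1, a mitochondrial protein that binds single-stranded DNA, was at 0.823 at 0 h, 0.264 at 5 h and 0.496 at 8 h (adjusted p = 0.0119). TCB3, a tether of the endoplasmic reticulum to the plasma membrane, was at 1.00 at 1 h, 0.539 at 5 h and 0.836 at 8 h (adjusted p = 0.0186). BDP1, a subunit of TFIIIB, was at 0.821 at 1 h, 0.320 at 6 h and 0.871 at 8 h (adjusted p = 0.0293). The genes named here were picked for their shape after their values were seen.

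The small nucleolar RNA snR86 was at 0.820 at 0 h, 0.415 at 5 h and 0.868 at 8 h. A site in 25S rRNA stayed between 0.967 and 0.993, although copies of the rDNA share reads, so values of single copies are uncertain. Among the 214 complete sites the lowest value lay at 7 h for 45, at 6 h for 37 and at 5 h for 35. Of the 7 complete glycolysis sites 4 were lowest at 7 h, against 41 of 207 others (Fisher's exact test, p = 0.0370, with 10 hours looked at and no adjustment). Some sites, such as CDC19 and TPI1 at 7 h and ATE1 and MLO50 at 3 h, had exactly the same value, and the precision of these values is unknown.

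The fall of the median to 6 h was set against 2 technical explanations. The median over all sites with a value in each library was 0.919 at 0 h and 0.828 at 6 h. A change in which sites gave a value is argued against as the whole cause by the sites with a value in all 10 libraries, whose median changed by -0.0704 from 0 h to 6 h. The fall reported first was over those same sites, so such a change cannot enter it. A lower yield of digestion cannot be told apart from a change at the sites by the 18S rRNA site: it was at 0.872 at 0 h, 0.705 at 6 h and 0.881 at 8 h, but at 0.665 at 1 h, 0.645 at 2 h and 0.639 at 3.5 h, lower than at 6 h, while the median was higher at those hours than at 6 h (0.909, 0.890 and 0.871 against 0.855). Its Pearson correlation with the median over the 209 complete sites outside rRNA and small nucleolar RNA was 0.0909 (permutation p = 0.801, adjusted p = 0.828 over 5 relations). The 95% interval, -0.571 to 0.682, was too wide over 10 libraries to decide. Spearman's rho was 0.0424 (permutation p = 0.919, adjusted p = 0.919). Without 2 h and 3.5 h, where the 18S value lay farthest from its own median over the libraries, r was 0.0869. The other noncoding sites did not decide it, as they moved in different directions. The 25S rRNA site was at 0.976 at 0 h and 0.982 at 6 h (r = -0.396, permutation p = 0.264, adjusted p = 0.534). The snR86 site was at 0.820 at 0 h and 0.610 at 6 h (r = 0.355, permutation p = 0.321, adjusted p = 0.534). Progress through meiosis, the course's own variable, stays open and untested.

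The 18 sites that fell in a line were set against chance and against a loss of digestion by the same factor at all sites. Of 100 orders of the libraries, the real one included, 1 gave as many sites, with 18 against at most 0 in the others, and the excess of falling over rising sites at an unadjusted p under 0.05 was 88 against at most 75, so chance order is argued against; for the windows 1 of 100 splits gave as many, with 18 against at most 4. After scaling each library by its median, the median slope of the 18 sites was -0.0483, with a median SE of 0.0116, against -0.0530 and 0.0114 before, but no site passed (adjusted p from 0.0541 to 0.533), why the calls ended was not tested beyond these medians, and sites picked for their fall would keep some of it. To allow for that, and added after these slopes were seen, the scaled libraries were put in 1000 orders, the real one included. The real medians were put back and the 18 sites with the smallest p among falling ones were picked anew in each order. The median moderated t after scaling was -4.13 in the real order against a median of -2.28 in the others (permutation p = 0.001). That argues against a loss by the same factor at all sites as the whole cause. A loss of digestion that differed between sites was not tested and stays open. Changes in which transcripts or isoforms were present, and in methylation, also stay open, as no RNA level or deletion control was analysed here.

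Cleavage stood higher at 8 h than at 6 h at some sites that had fallen, but at only 4 of the 11 sites that fell in a line and had a value at 8 h. Across 215 sites, which are not independent, the fall from 0 and 1 h to 3 to 5 h was related to the change from 6 h to 8 h, with Spearman's rho = -0.273 (95% interval -0.392 to -0.144, permutation p = 7e-05; Pearson's r = -0.333; rho = -0.190 on the logit scale, 95% interval -0.316 to -0.0580). The limit set beforehand against a shift of the 8 h library alike at all sites was a rho under -0.2, which rho passed but the upper end of its interval and the logit value, added after rho was seen, did not, so that shift stays open. Of 40 sites that had fallen by over 0.1, 30 (75%) were higher at 8 h, with a median change of 0.0752, against 107 of 175 others (61.1%), with 0.0153, and lower precision of the 8 h library, with 626 sites listed, stays open because 75% lies at the limit set beforehand. A return of cleavage late in the arrest may be a hypothesis to test with a repeat of the 7 h and 8 h libraries.

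Sites of 1 gene were asked whether their slopes lay closer together than those of different genes. Over 63 pairs in 57 genes the median absolute difference of slopes was 0.0171 per hour, against 0.0135 in permutations of slopes over sites (permutation p = 0.925), so no closeness was found.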
